A study of Mus musculus with 2 samples.

How the data were processed

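Total RNA from the forebrains of 2 newborn mice, pup 1 (replicate 1) and pup 3 (replicate 2), was measured in 1 library each, and both formed 1 group, so no contrast between conditions was available. Per the labels, RNA was extracted with the mirVana kit, 10 ng went into each library, RNA longer than 200 nt was used and spike-in RNAs were added, and the labels link the manual of a SMARTer low-input kit. The labels describe single forebrains from pup 1 and pup 3, although both carry the same donor identifier, and give the sex as not collected. Per the deposited notes, reads were quantified on mouse assembly mm10 with the GENCODE M4 annotation; the aligner, the quantifier, their versions and the strandedness are not given in the sources used here. The deposited gene and transcript tables give expected counts, which divide reads shared by several features and need not be whole. They also give TPM per the file headers, which sum to nearly the same total in both libraries, with a posterior mean TPM and the bounds of a credibility interval whose level is not given in the sources used here. The transcript tables give the deposited share of each transcript in its gene's TPM as a percent. The intervals bracket the posterior mean TPM in 100% of genes with a posterior mean above 0.5 TPM. An interval around that estimate holds it nearly by construction, so this is no test of the intervals. They need not hold the TPM used for levels and ratios: Tuba1a had 17500.7 TPM in pup 1 and an interval of 17054 to 17145. The rule for differing genes thus combines a ratio of TPM with intervals around another estimate.

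Each gene table held 69691 entries: 43346 genes, 26248 entries with numeric identifiers and tRNA-like lengths, 96 ERCC spike-ins and phiX. Expected counts totalled 40066386 in pup 1 and 40431595 in pup 3. Gene symbols, biotypes and positions came from GENCODE M21 on GRCm38, the same build as mm10, with identifiers matched without version; 42462 genes matched, and the 884 others held 0.171% and 0.154% of counts and were kept without a symbol. Symbols shared by 2 identifiers (20) were left out of the lists. Reads shared by near-identical copies were divided by the authors' quantification, TPM of very short genes is inflated by small effective lengths, and antisense or overlapping genes cannot be separated without strand. FPKM and posterior counts in the tables were not used here.

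Groups, tests, 44 gene lists, 24 gene pairs, 24 isoform genes and most alternatives were fixed before the data were examined. Genes were detected at TPM of 1 or more in both pups. A list's level was the median over measured members of the mean TPM, with its percentile among 13030 detected protein-coding genes; 450 of 459 listed genes were measured. Pair ratios were log2 of TPM + 0.1 in each pup, taken as larger than the pup spread where the mean exceeded 3 SD with 1 sign. Ratios between pups were pup 3 over pup 1 of TPM + 0.1, which understates the change of low genes. Genes differed where the mean TPM was 1 or more, the ratio 2-fold or more and the deposited intervals, assumed beforehand to be 95% intervals, did not overlap. A list's median ratio was placed among 10000 random lists of its size matched on mean TPM in 50 bins. The biological coefficient of variation came from edgeR 4.0.16 (TMM, filterByExpr with a minimum count of 10, intercept only) on expected counts rounded to whole numbers, with R 4.3.3; size factors of DESeq2 1.42.0 were an alternative. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

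The named genes were the 10 nuclear protein-coding, 5 mitochondrial and 5 noncoding genes with the highest mean TPM, the 2 highest members and the lowest member of each list with others where needed, the genes of described pairs, the 10 differing genes with the largest ratios in each direction, the isoform genes and the 5 highest spike-ins; some genes that this rule names are not reported here. The alternatives were other thresholds, pseudocounts and filters, posterior mean TPM, TMM and ERCC scaling, an exact binomial test, each pup alone, rescaled TPM, library-scaled counts and shares of counts. Matching on length and a correction for length, level and GC content by a quadratic fit across genes were added after the data were seen, as were lists of further diencephalic and cortical markers, of X-linked genes that escape inactivation and of neutrophil genes; GC content was available for 99.4% of genes with a mean TPM of 1 or more. On simulated libraries of 14788 genes with Poisson counts, the 2-fold rule with counting intervals recovered 50% of 50 genes changed 2-fold, 96% of those changed 3-fold and 100% of those changed 4-fold or 8-fold, with 4 false calls. Those libraries held counting error only, whereas the real ones differed by more and the rule used deposited intervals. The simulation therefore gives no error rate for the genes called here. The simulated spread of 0.2 was estimated as 0.199 over 17012 genes. Of 20 simulated lists of 12 genes shifted by -1 on the log2 scale 20 were found, as were 2 of 40 unshifted lists. That shift is larger than the median ratio of most lists below, so smaller shifts were not simulated.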

Results

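Total RNA was sequenced from the forebrains of 2 newborn mice (strain B6NCrl, postnatal day 0), a single forebrain per library, from 10 ng of RNA longer than 200 nt. Pup 1 was labelled replicate 1 and pup 3 replicate 2, and both belong to 1 group. The labels state no treatment or second tissue, and the sex of the pups was not recorded. The deposited expected counts summed to 40066386 in pup 1 and 40431595 in pup 3. Levels are given as deposited TPM, the abundance of a transcript relative to all others in its library, as the mean of both pups ± SD with n = 2 unless both pups' values are given. With 2 animals an exact two-sided sign-flip test cannot go below p = 0.5, so levels and ratios are set beside the spread between the pups and no test between conditions was made.

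The most abundant genes were considered first. Tuba1a, the alpha-tubulin of growing neurons, led the nuclear protein-coding genes at 19430.4 ± 2729 TPM (chromosome 15, 98949837 to 98953703, build mm10). Actb, cytoplasmic beta-actin, reached 8992 ± 267 TPM (chromosome 5, 142903115 to 142906754), and Stmn1, a microtubule-destabilizing protein, 6668 ± 506 TPM (chromosome 4, 134468320 to 134473843). Nnat, an imprinted gene of the developing brain, had 5696 ± 589 TPM (chromosome 2, 157560078 to 157562522). The actin-binding thymosins Tmsb4x and Tmsb10 stood at 5557 ± 835 and 5331 ± 459.8 TPM. Ppia (cyclophilin A), Ftl1 (ferritin light chain), Ubb (polyubiquitin B) and Actg1 (gamma-actin) completed the 10 highest, with 5272 ± 790.1, 5002 ± 254, 4096 ± 153 and 3616 ± 280.2 TPM. In all, 14389 genes had a TPM of 1 or more in both pups, of which 13030 were protein-coding, 391 processed pseudogenes, 236 antisense genes and 212 lincRNA genes. A TPM of 10 or more in both pups was reached by 8143 genes, 100 or more by 1637 and 1000 or more by 98. The 10 most abundant genes took 9.67% of TPM in pup 1 and 12.7% in pup 3.

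Nuclear protein-coding genes held 83.2% ± 2.47 of TPM, and the 13 mitochondrially encoded protein-coding genes 5.04% ± 0.988. mt-Atp6 and mt-Atp8, subunits of ATP synthase, were the highest of the mitochondrial genome at 13038 ± 3150.1 and 11523 ± 2241 TPM. The large mitochondrial ribosomal RNA mt-Rnr2 followed at 6953 ± 1234 TPM, then mt-Nd1 at 5549 ± 739 and mt-Cytb at 4790.2 ± 927 TPM. The 2 mitochondrial ribosomal RNAs together took 0.896% ± 0.139 of TPM. LincRNA genes held 0.932% ± 0.151 and processed pseudogenes 2.54% ± 0.292. By expected counts, the nuclear protein-coding share was 94.1% in pup 1 and 92.5% in pup 3, since TPM weights short transcripts more. Among noncoding genes outside the mitochondrial genome, Gm28437 led at 13994 ± 1961 TPM (chromosome 1, 24613189 to 24613971), followed by the 7SL RNA copies Rn7s2 and Rn7s1 at 12504 ± 4541 and 12502 ± 4541 TPM, then Gm29216 at 5743 ± 772 and Gm10123 at 4591 ± 548 TPM. These values are uncertain, as is that of the processed pseudogene Gm10123: Rn7s1 and Rn7s2 are near-identical copies, and Gm28437 and Gm29216 lie in a cluster of unprocessed pseudogenes on chromosome 1 that resembles the mitochondrial genome, so that shared reads were divided between copies. Mitochondrial genes that share reads with this cluster are uncertain too, as are their order and the mitochondrial share of TPM. In pup 1 the deposited interval ran from 1560 to 10982 TPM for mt-Co3 and from 7474 to 12609 TPM for mt-Atp6.

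Genes of immature neurons formed the most abundant neural list. Its 12 members had a median of 1221 TPM, at percentile 99.5 of detected protein-coding genes, with 1270.5 and 1177 TPM in pups 1 and 3, and all 12 exceeded 100 TPM in both pups. Stmn1 was highest, Marcksl1 had 1942 ± 44.8 TPM, Tubb3, the neuronal beta-tubulin, 1768 ± 95.8, Gap43, a growth cone protein, 1515 ± 252, and Dcx, the migration protein doublecortin, was the lowest at 157 ± 42.3. Markers of synapses and mature neurons had a median of 71.2 TPM (percentile 82.2), from Vamp2 at 448 ± 45.8 and Snap25 at 191 ± 69.8 to the heavy neurofilament Nefh at 2.37 ± 0.721. The glutamatergic list had a median of 44.6 TPM, with Neurod6 at 268 ± 87.1 and Gria2 at 111 ± 38 the highest and Nrn1 at 25.4 ± 6.67 the lowest. GABAergic genes had a median of 35.5 TPM, led by Dlx1 at 104 ± 23.7, with Dlx6 lowest at 3.69 ± 0.884. Cortical interneuron subtype markers were uneven, with a median of 8.77 TPM (12 and 5.65 TPM in pups 1 and 3): the neuropeptides Sst and Npy had 537 ± 18.5 and 407 ± 180.0 TPM, while Vip had 0.675 ± 0.0354 and the late marker Pvalb 1.97 ± 0.658.

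Upper-layer cortical markers had a median of 13 TPM and deep-layer markers 33.2 TPM. Lmo4 at 219 ± 9.04 and Cux1 at 71.5 ± 3.92 led the upper-layer list and Rorb at 7.94 ± 3.39 closed it, whereas Crym at 127 ± 30.5 and Bcl11b (CTIP2) at 48.9 ± 16.2 led the deep-layer list and Zfpm2 at 7.91 ± 1.84 closed it. Striatal projection neuron genes had a median of 15.4 TPM, with Foxp1 at 128 ± 21.3, the tachykinin precursor Tac1 at 91.7 ± 2.24 and the dopamine receptor Drd2 lowest at 4.84 ± 1.31. The Cajal-Retzius list had a median of 4.62 TPM, although Calb2 reached 197 ± 70.9 and Reln, the secreted signal of these cells, 32 ± 3.22, with Lhx5 at 2.25 ± 1.44. Olfactory bulb and neuroblast genes had a median of 7.11 TPM, from Dlx2 at 35.3 ± 2.88 and Cdhr1 at 10.4 ± 2.31 to Tbx21 at 2.17 ± 0.382. Neuropeptide genes had a median of 39.7 TPM, with Vip again the lowest.

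Radial glia and neural progenitor genes had a median of 13.8 TPM, with Fabp7, a fatty-acid binding protein of radial glia, at 2345 ± 123, the intermediate filament Vim at 213 ± 33.4 and Gli3 at 2.26 ± 0.905. The cell division list had a median of 16.6 TPM, with all 12 members at 1 TPM or more in both pups, from Pcna at 110.1 ± 4.14 and Cdk1 at 43.4 ± 3.17 to Mki67 at 2.4 ± 0.594. Intermediate progenitor genes had a median of 4.22 TPM, with Neurod1 at 31 ± 8.81, Gadd45g at 29.4 ± 0.375 and Neurog1 lowest at 0.025 ± 0.0354. Microcephaly-associated genes had a median of 2.4 TPM, with Nde1 at 13.9 ± 1.92, Cdk5rap2 at 4.47 ± 0.424 and Kif14 at 0.25 ± 0.099.

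Among genes of forebrain regional identity, Nr2f1 was highest at 66.1 ± 11.4 TPM and Gsx2 lowest at 1.38 ± 0.205 TPM, with a list median of 20.4 TPM. The midbrain and hindbrain list had a median of 0.005 TPM, and 1 of its 14 members, tyrosine hydroxylase (Th, 7.12 ± 0.417 TPM), reached 1 TPM in both pups. Tph2 was the next highest at 0.78 ± 0.184 TPM, and the hindbrain gene Hoxa2 was at 0 in both pups. Diencephalic and hypothalamic genes had a median of 4.57 TPM, with 6.99 and 3.01 TPM in pups 1 and 3. Tcf7l2, a thalamic transcription factor, had 168 ± 106 TPM, the vasopressin precursor Avp 113 ± 62.3 TPM and Rax 0.025 ± 0.0354 TPM. Genes of skin, muscle, bone and lens had a median of 0.21 TPM, with Acta1 at 16.1 ± 2.48 and Krt10 at 10.3 ± 0.997 the highest and Krt5 at 0.02 ± 0 the lowest.

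**Figure D1:**
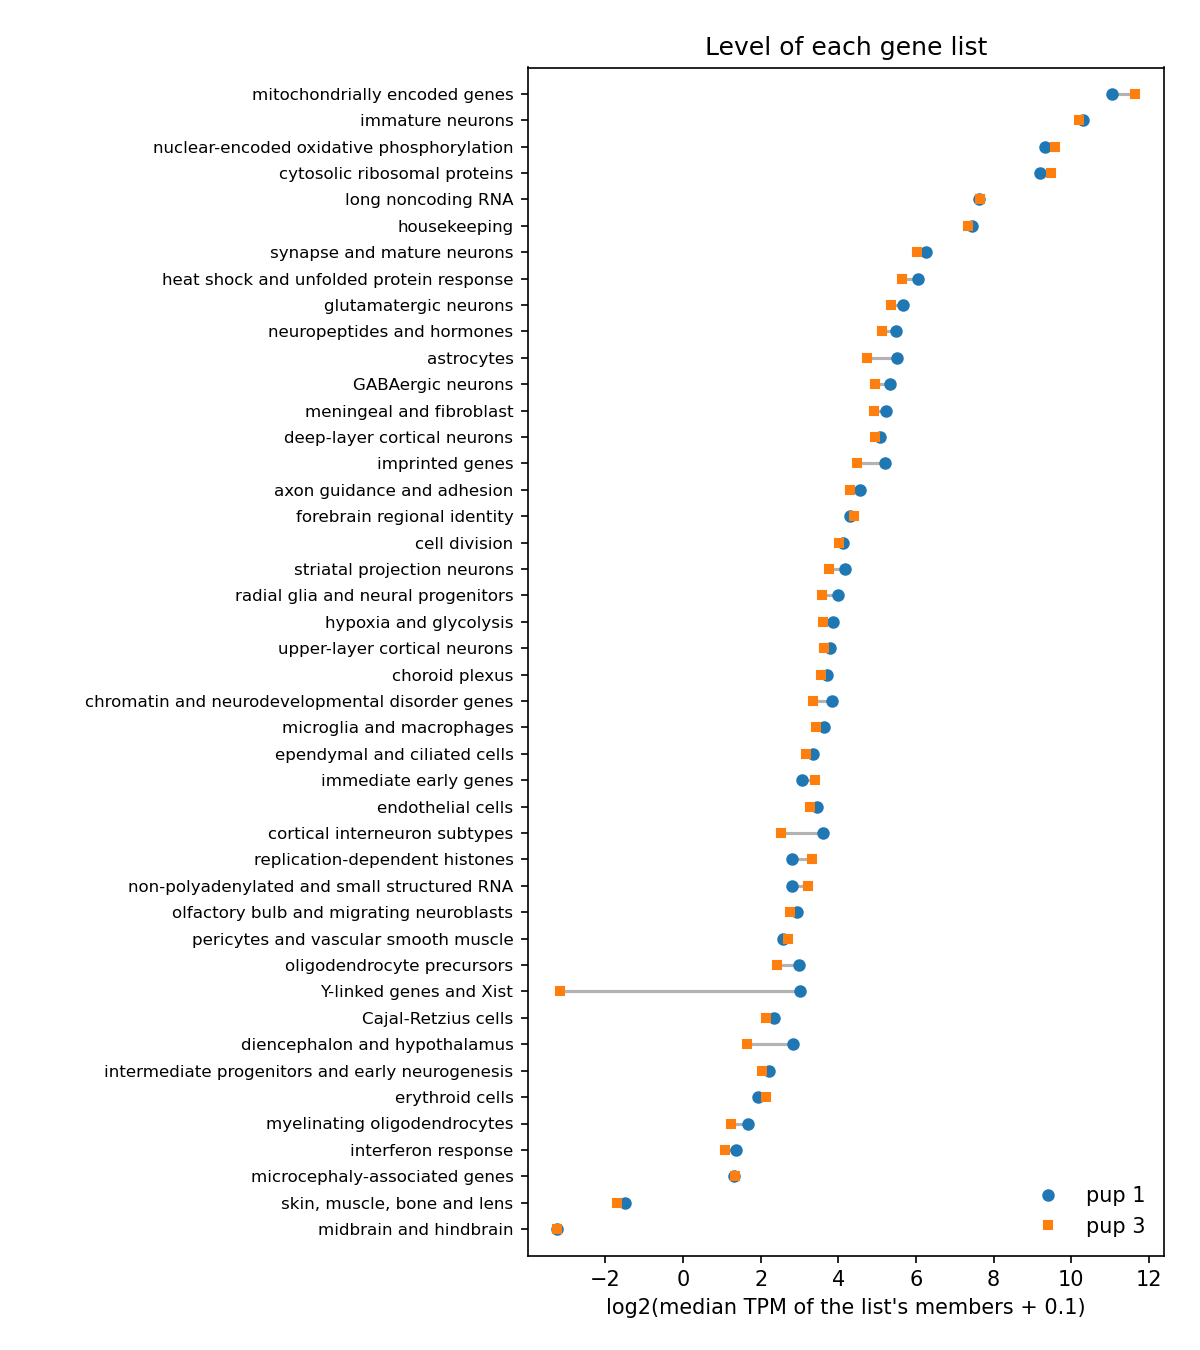
Level of each of the 44 gene lists, as log2 of the median TPM of its members plus 0.1, in pup 1 (circles) and pup 3 (squares), with a line joining the pups. Mitochondrially encoded genes (median 2659.9 TPM) and immature neuron genes (1221 TPM) are at the top, and midbrain and hindbrain genes are at the bottom.

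Astrocyte genes had a median of 36 TPM, led by Apoe at 1171 ± 160.5 and Aldoc at 171 ± 28.1, with S100b at 2.73 ± 0.53. Oligodendrocyte precursor genes had a median of 6.55 TPM, with Olig1 at 113 ± 9.62, Olig2 at 11.6 ± 2.29 and Gpr17 at 2.4 ± 1.05. Myelinating oligodendrocyte genes were lower, at a median of 2.67 TPM: Cldn11 had 44.5 ± 8.68 TPM, Cnp 43 ± 8.14 and Opalin 0.01 ± 0.0141. Among non-neural cells, microglia and macrophage genes had a median of 11 TPM (C1qb 61.7 ± 4.68, Pf4 54.4 ± 6.82, Mrc1 3.25 ± 0.375), and endothelial genes 9.35 TPM (Cldn5 112 ± 3.44, Slc2a1 37.5 ± 0.403, Slco1a4 2.37 ± 0.233). Pericyte and vascular smooth muscle genes had a median of 6.79 TPM (Rgs5 12.6 ± 0.509, Kcnj8 8.2 ± 0.212, Myh11 0.425 ± 0.00707), and meningeal and fibroblast genes 33.9 TPM (Igf2 126 ± 5.31, Dcn 53.8 ± 18, Foxc1 2.6 ± 0.297). The choroid plexus list had a median of 12.2 TPM, with the thyroid hormone carrier Ttr at 1189 ± 207, Enpp2 at 54.7 ± 3.1 and Kl at 0.425 ± 0.134. Ependymal genes had a median of 9.53 TPM, from Dynlrb2 at 26.6 ± 4.14 and Foxj1 at 15.2 ± 2.96 to Ccdc153 at 2.69 ± 0.587. Erythroid genes had a median of 4.01 TPM, but the adult globins were abundant, with Hba-a2 at 1236 ± 264 and Hbb-bs at 689 ± 218 TPM, and the embryonic Hba-x was at 0 in both pups. Hba-a1 and Hba-a2 are near-identical, so the division of counts between them is uncertain.

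The mitochondrially encoded list had a median of 2659.9 TPM, with mt-Nd4l lowest at 62.3 ± 46.8. That median is the value of mt-Co3, which is uncertain because of its wide interval. Nuclear-encoded oxidative phosphorylation genes had a median of 705 TPM, from Atp5b at 1836 ± 55 and Cox6c at 1226 ± 215 to Cycs at 69.5 ± 5.89. Cytosolic ribosomal protein genes had a median of 644 TPM, from Rpl32 at 1155 ± 149 and Rplp1 at 1028 ± 223 to Rpl5 at 60 ± 3.34. Housekeeping genes had a median of 165 TPM, with Gusb lowest at 24.1 ± 1.65. Hypoxia and glycolysis genes had a median of 13.3 TPM, with lactate dehydrogenase Ldha at 654 ± 2.7, Pgk1 at 185 ± 8.61 and Car9 at 0.58 ± 0.0141. The heat shock and unfolded protein list had a median of 56.8 TPM, with the chaperone Hspa5 at 247 ± 6.19, Hsp90b1 at 152 ± 15.4 and Hspa1b at 0.395 ± 0.0495. Interferon response genes were low, with a median of 2.41 TPM, Bst2 at 17.6 ± 0.594 and Mx1 at 0.26 ± 0.283. Immediate early genes had a median of 9.38 TPM, with Jun at 41.2 ± 3.11, Dusp1 at 31.6 ± 0.608 and Fosb at 0.255 ± 0.0354.

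Imprinted genes had a median of 28.8 TPM, and all 17 were at 1 TPM or more in both pups, with Ndn, second to Nnat, at 1159 ± 172 and Zrsr1 lowest at 2.92 ± 0.544. Long noncoding RNAs of the fixed list had a median of 203 TPM, with Malat1 at 1859 ± 1328, Gm26917 at 938 ± 118 and Kcnq1ot1 at 0.345 ± 0.29. The value of Malat1 is uncertain: its mean transcript length was 532 nt at a locus from 5795690 to 5802672 on chromosome 19. Gm37376 lies within that locus on the opposite strand, with 11863 counts in pup 1 against 29877 for Malat1, and strand use is not stated. Small structured RNAs had a median of 8.01 TPM: 7SK (Rn7sk) had 284 ± 53.1 TPM and Rny3 was at 0 in both pups. Replication-dependent histone genes had a median of 8.38 TPM, led by Hist1h4d at 99.5 ± 33.5 and Hist1h2bc at 48.4 ± 5.01, with Hist1h2bb at 0.3 ± 0.0707. Axon guidance and adhesion genes had a median of 22 TPM, with L1cam at 75.6 ± 16.9, Epha4 at 44.3 ± 9.01 and Ntn1 at 4.22 ± 1.31. Chromatin and neurodevelopmental disorder genes had a median of 12.1 TPM, with Tcf4 highest at 241 ± 52.7. Of the 44 lists, 42 had a median of 1 TPM or more and 17 lay above the median of detected protein-coding genes, 17 TPM. With members of 1 TPM or more only, medians were over 1.5 times higher for erythroid (507 TPM), small structured RNA (37), myelinating oligodendrocyte (16.1), diencephalic (11.5), midbrain and hindbrain (7.12, Th alone), skin and muscle (10.3), immediate early (17.8) and neuropeptide genes (66.4). With posterior mean TPM the mitochondrially encoded list was at 4018 TPM and the midbrain and hindbrain list at 0.04 TPM.

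Ratios between paired genes, such as an early and a late form, were taken within each library on TPM + 0.1, and 20 of 24 had a mean log2 ratio over 3 SD with the same sign in both pups. Grin2b, the early NMDA receptor subunit, was 15.1 and 31.6 times Grin2a, the later one, in pups 1 and 3 (log2 4.45 ± 0.75). The sodium channel gene Scn3a was 2.97 and 2.91 times Scn1a (log2 1.56 ± 0.018), and Fabp7 was 49.4 and 91.6 times Gfap (log2 6.07 ± 0.63). The oligodendrocyte precursor gene Pdgfra was 9.78 and 12.1 times the myelin gene Mog. The chloride exporter Slc12a5 (KCC2) was 5.08 and 3.53 times the importer Slc12a2 (NKCC1) (log2 of Slc12a2 over Slc12a5 -2.08 ± 0.37). The medium neurofilament Nefm was 18.7 and 18.4 times Nefh, and Camk2b 6.28 and 7.001 times Camk2a. Adult beta-globin Hbb-bt was 310.2 and 306 times embryonic Hbb-y. The pyruvate kinase gene Pkm was 2240.5 and 4368 times Pklr, which was near 0. Dnmt3a was 43.9 and 35 times Dnmt3b, Gad1 2.41 and 2.54 times Gad2, and Sox11 10.2 and 11.7 times Sox2. With a pseudocount of 1, which lowers the ratio where 1 gene is low, the mean log2 ratio was 3.69 for Grin2b over Grin2a, 2.45 for Pdgfra over Mog, 7.31 for Hbb-bt over Hbb-y, 4.60 for Dnmt3a over Dnmt3b and 9.06 for Pkm over Pklr (11.61 ± 0.68 with 0.1). With library-scaled counts, not divided by length, it was 4.23 for Fabp7 over Gfap, 5.45 for Pdgfra over Mog, 5.25 for Sox11 over Sox2 (3.45 ± 0.14 on TPM), 5.57 for Grin2b over Grin2a, 2.69 for Scn3a over Scn1a, 12.26 for Pkm over Pklr, 1.27 for Kif5c over Kif5b and 1.37 for Drd1 over Drd2. The smallest ratio past the criterion was Kif5c over Kif5b, 1.17 and 1.14. In 4 pairs the mean log2 ratio did not exceed 3 SD, among them Slc17a6 over Slc17a7 (1.07 and 0.494) and Drd1 over Drd2 (0.993 and 1.23).

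Isoform shares were estimated for 24 genes, and 22 had the same leading transcript in both pups. Snap25-201 carried 78.2% ± 2.31 of the TPM of Snap25, a vesicle fusion protein, and Mapt-205 47.6% ± 0.721 of that of Mapt, the microtubule protein tau. The leading transcript of Bin1 held 82.1% ± 1.31, that of Ncam1 76.3% ± 0.891, that of Rbfox1 87.7% ± 0.29 and that of Clta 66.2% ± 0.148. Mef2c-203 carried 73.5% ± 2.14 and Cdc42-201 70.5% ± 1.68. The leading transcript held less in Ank2 (28.8% ± 3.24). Transcripts annotated as retained introns led for Agrn (53.1% ± 2.6), Kif1b (46.7% ± 1.82) and Fn1 (41.4% ± 1.43). For Dclk1, Dclk1-203 held 47.5% and 40.5% in pups 1 and 3 and Dclk1-201 42.3% and 45.4%, so the order changed, as it did for Tpm1 between Tpm1-209 (27.8% and 23.7%) and Tpm1-206 (20.5% and 23.8%). Among leading transcripts the widest gap was that of Meg3-205 of the noncoding RNA Meg3 (53.2% and 39.1%), and Grin1-202, not a leading transcript, held 21.2% and 5.96%. Overlapping transcripts share reads, so these shares are model estimates.

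Pearson's r of log2(TPM + 1) was 0.985 and Spearman's rho 0.984 over 14985 genes with a mean TPM of 1 or more, a correlation across genes, which are not independent replicates. Of these genes, 94.5% were within 2-fold between the pups, and 80.4% were lower in pup 3, or 51.1% after TMM scaling. The common biological coefficient of variation was 0.17 over 16815 genes (edgeR on rounded expected counts), and 0.219, 0.167 and 0.147 from the lowest to the highest of 3 equal groups of genes by count. The libraries differed by more than counting error, as a chi-square test of counts, which covers counting error only and cannot tell separate animals from separate preparations, gave a statistic 56.5 times its degrees of freedom over 17485 genes. ERCC spike-ins, synthetic RNAs added to each sample, took 334 counts in pup 1 and 278 in pup 3, or 0.000834% (exact Clopper-Pearson 95% interval 0.000747 to 0.000928) and 0.000688% (0.000609 to 0.000773), intervals that cover counting error only. ERCC-00074 had 86 and 60 counts in pups 1 and 3, ERCC-00130 63 and 55, ERCC-00096 57 and 57, ERCC-00002 53 and 47, and ERCC-00004 12 and 14. Across the 24 spike-ins detected in either pup, r was 0.979.

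**Figure D2:**
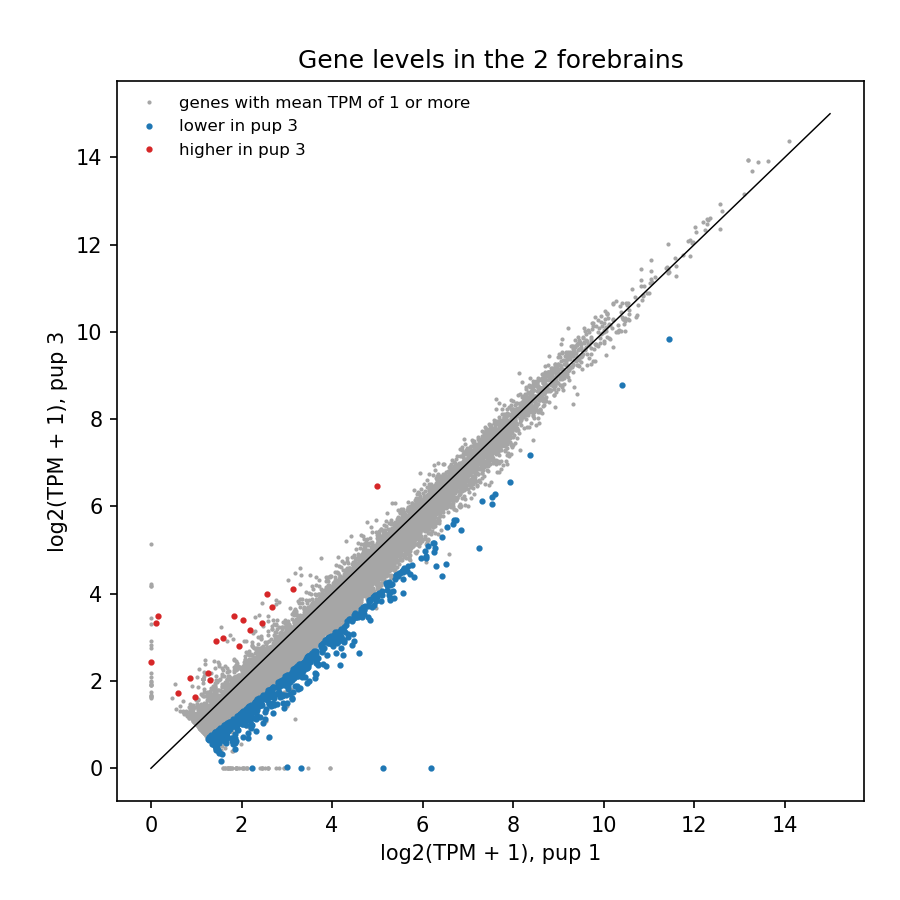
Gene levels in the 2 forebrains, as log2(TPM + 1), with pup 1 on the horizontal and pup 3 on the vertical axis, for genes with a mean TPM of 1 or more. Coloured points mark the 577 genes lower and the 19 genes higher in pup 3 by the 2-fold and interval criterion, and the diagonal marks equal values; with ERCC scaling the split was 106 lower and 116 higher.

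Between the 2 forebrains, sex-linked genes differed most. The Y-linked genes Eif2s3y (chromosome Y, 1010543 to 1028847), Ddx3y and Kdm5d had 2555, 3115 and 676 counts in pup 1 and 0 in pup 3. Against a floor of 3 counts in the library that is at least 852-fold, 1038-fold and 225-fold more, by counting error only. The deposited intervals allow smaller gaps, with lower bounds of 66.9, 31.6 and 7.70 TPM in pup 1 and upper bounds of 0.564, 0.220 and 0.279 TPM in pup 3. Uty had 619 counts against 1, a ratio of 619 (exact interval of counting error 111 to 24488). Xist (chromosome X, 103460366 to 103483254), the RNA of the inactive X chromosome, had 2.18 counts in pup 1 and 4462 in pup 3, a ratio of 2047 (617 to 18428), while its TPM was 0.08 and 8.98, a log2 ratio of 5.66 on TPM + 0.1. Its deposited interval reached 0.681 TPM in pup 1 and began at 8.65 TPM in pup 3, so the gap can be smaller than the count ratio. Tsix, with a log2 ratio of 5.63, overlaps Xist on the opposite strand, and since strand use is not stated the values of both are uncertain. The list of these 6 genes had a median of 4.87 TPM (7.93 and 0.01 TPM in pups 1 and 3) and a median log2 ratio of -6.19 (percentile 0 of matched lists).

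With these included, 596 of 14985 genes were at least 2-fold apart with deposited intervals that did not overlap, 577 lower and 19 higher in pup 3 (96.8% lower). TMM scaling, which raised pup 3 by 0.26 on the log2 scale, gave 252 genes, 208 lower and 44 higher (82.5% lower), and ERCC scaling, which raised it by 0.44, gave 222 genes, 106 lower and 116 higher (47.7% lower). The other genes at the low end were 2900037B21Rik, with 22 counts in pup 1 and 0 in pup 3 (at least 7.33-fold), the antisense gene Gm15202 with 14 against 1 (ratio 14, 2.13 to 592), Gm37219 (log2 ratio of pup 3 over pup 1 -2.80), 2900022M07Rik (-2.60), Gm6525 (-2.38) and a gene ID without a symbol in the annotation used (-2.53). At the high end, the lincRNA Gm26735 (chromosome 13, 28943048 to 28951671) had 0 counts in pup 1 and 315 in pup 3, at least 105-fold more, although the upper bound of its deposited interval in pup 1 (1.94 TPM) lay close to the lower bound in pup 3 (2.08 TPM). Further genes higher in pup 3 were the small heat shock protein Hspb3 (1.93), Gm5483 (1.99), Gm16379 (1.89), Gm5453 (1.85), Stfa1 (1.74) and the neutrophil proteins S100a8 (1.59) and S100a9 (1.58), of which Gm16379 and Gm5453 are processed pseudogenes with uncertain values, as are those of Stfa1 and Gm5483, which belong to a family of similar genes. These values compare 2 libraries and not conditions, and the difference has no replicate check.

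Gene lists were then compared between the pups. The median log2 ratio over 14985 genes was -0.27, so each list was set against 10000 random lists matched on mean TPM, and 22 of 44 lists lay outside the central 95%. By chance 2.2 would lie outside if genes varied independently of each other. Genes of a list can vary together, lists can share genes and each pup has 1 library, so these counts give no significance. Diencephalic and hypothalamic genes stood lowest apart from the sex-linked list, with a median of -1.27 (percentile 0) and all 11 members lower in pup 3, as with TMM scaling, against 9 of 11 with ERCC scaling. Tcf7l2 had 243 and 93.1 TPM in pups 1 and 3, Lhx9 23 and 5.26, Avp 157 and 69, the orexin precursor Hcrt 6.94 and 2.19 and the oxytocin precursor Oxt 6.99 and 1.82. Long noncoding RNAs had a median of -0.98 (percentile 0), with 9 of 11 members lower in pup 3 and 7 with TMM or ERCC scaling: Snhg11 had 150.2 and 32.1 TPM and Malat1, whose values are uncertain, 2799 and 920.1, whereas Pantr1 had 197 and 352. After correction for gene length, level and GC content the median was -0.58, percentile 0. Glutamatergic genes (-0.54, percentile 0.12) held both directions, Slc17a6 with 43.1 and 20.3 TPM and Neurod6 with 206 and 329. Also lower than matched lists were Cajal-Retzius (-0.75, percentile 0.835), GABAergic (-0.47, 0.97), deep-layer (-0.49, 1.27), synapse (-0.47, 0.21), chromatin (-0.53, 1.16), imprinted (-0.38, 1.11) and immature neuron genes (-0.20, 0.2), although the median of immature neuron genes was above 0 with TMM and ERCC scaling and that of imprinted genes with ERCC scaling. All members of the Cajal-Retzius, GABAergic, synapse and chromatin lists were lower in pup 3, against 4 of 7, 6 of 10, 6 of 12 and 9 of 12 with ERCC scaling. With random lists matched on gene length too, immature neuron genes lay inside the central 95% (percentile 21.4), as did deep-layer (6.79) and chromatin genes (11.5).

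On the other side, replication-dependent histones had a median of 0.41 (percentile 100), with 11 of 12 members higher in pup 3 and 12 of 12 with TMM or ERCC scaling, and small structured RNAs 0.76 (percentile 100), with Rny1 alone lower under each scaling. The latter median lies between the uncertain values of the near-identical Rn7s1 and Rn7s2, and was 0.45, percentile 99.97, after correction for length, level and GC content. Erythroid genes (0.43, percentile 99.97) included Hbb-bs at 535 and 843 TPM, and all 16 ribosomal protein genes were higher in pup 3 under each scaling (0.25, percentile 98.5). Of the 13 mitochondrially encoded genes, 12 were higher under each scaling (0.27, percentile 98.6). Both scalings raise pup 3, so genes that were higher there as deposited had to stay higher, and scaling was no check on them. Ratios near 0, all above 0 with TMM or ERCC scaling, that exceeded those of matched lists were seen for immediate early (0.017, percentile 99.8), cell division (-0.0076, 99.8), microglial (-0.071, 98.9), endothelial (-0.063, 98.2), pericyte (-0.027, 97.9) and intermediate progenitor genes (-0.051, 97.7). Matching on length as well brought ribosomal protein (93.9) and microglial genes (88) inside and placed upper-layer (99.9) and meningeal genes (99.2) outside, and 16 lists were outside with both matchings and after correction for length, level and GC content. That correction brought intermediate progenitor genes inside (91.2), with microglial (91.8), deep-layer (32) and chromatin genes (7.2), and placed interneuron subtype (1.47), astrocyte (1.44), upper-layer (99.1), meningeal (99.8) and olfactory genes (98) outside. With matching on level alone, the other 22 lists lay within the central 95%, from astrocyte (3.62) to meningeal genes (96.3), among them radial glia (percentile 17.1), upper-layer (89.2), striatal (29.4), housekeeping (32.8) and forebrain identity genes (73.2).

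**Figure D3:**
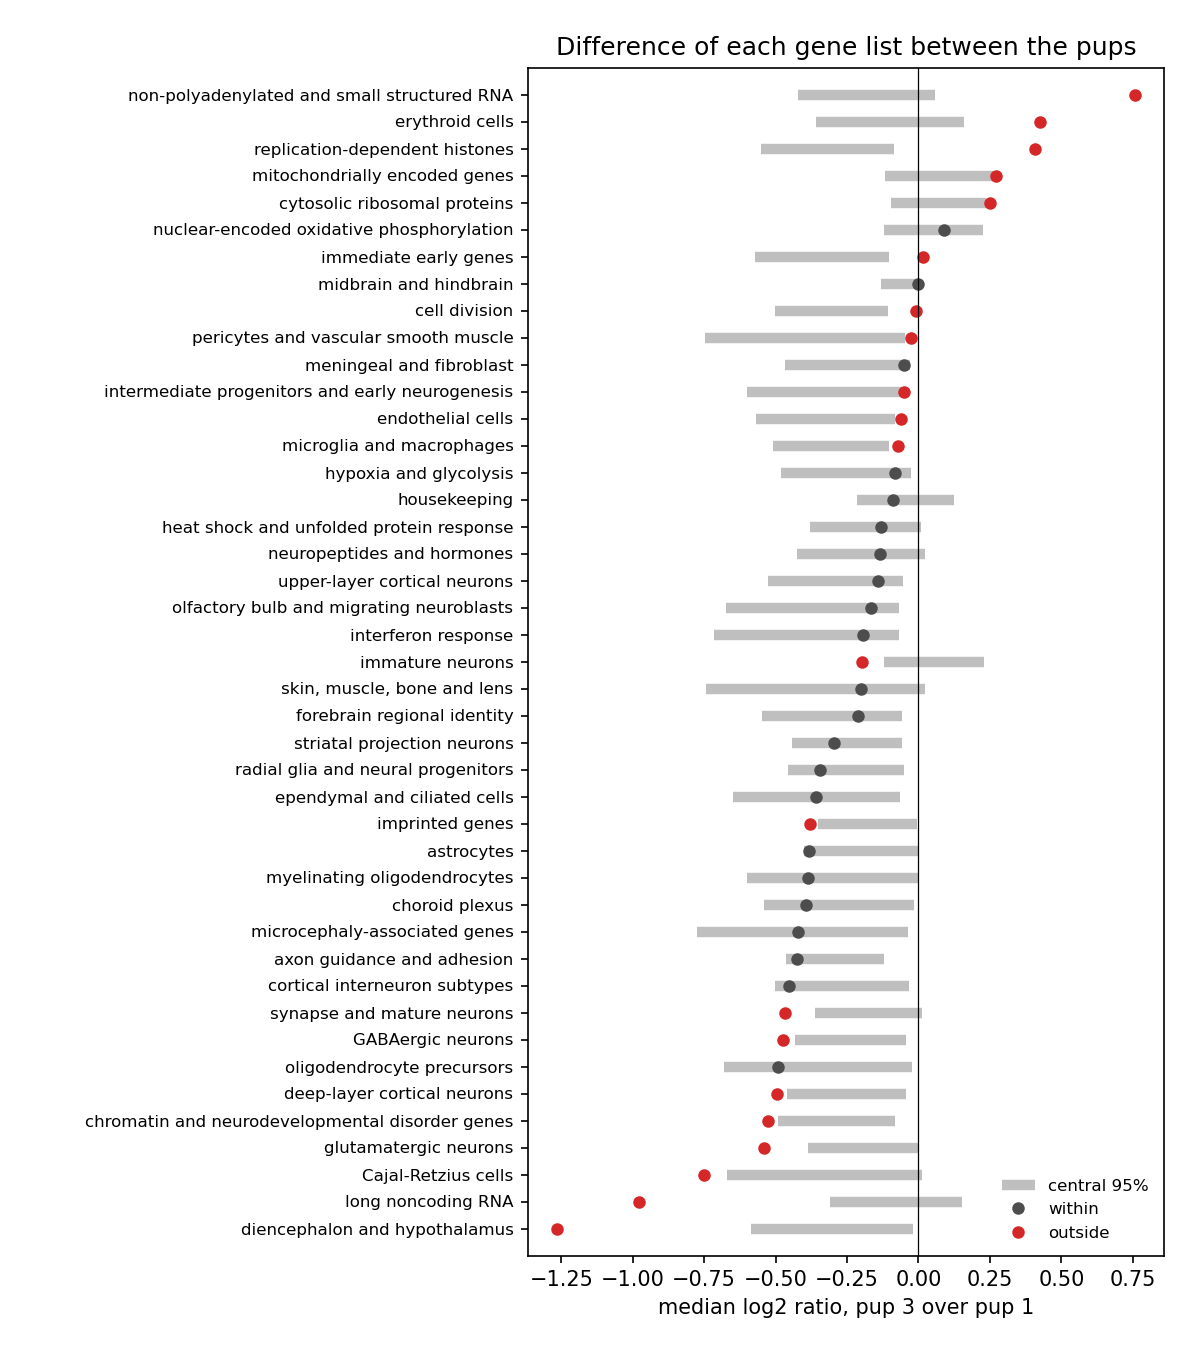
Median log2 ratio of pup 3 over pup 1 for 43 gene lists, without the sex-linked list, on the horizontal axis; grey bars give the central 95% of 10000 random lists matched on mean TPM, and red points lie outside. Values are without the TMM shift of 0.26: diencephalic and hypothalamic genes are the lowest at -1.27 and small structured RNAs the highest at 0.76. After correction for length, level and GC content small structured RNAs were at 0.45. They were then below histones (0.55). Midbrain and hindbrain genes, with a median of 0 as deposited, were at 0.57 after correction, inside the central 95% of matched lists (percentile 96.6). Most of them were below 1 TPM, and the correction was fitted on genes with a mean TPM of 1 or more, so that value is no evidence of a difference.

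Gene length moved with the ratio between the pups. In 8 groups of genes by transcript length, the median log2 ratio went from 0.064 in the shortest (101 to 914 nt, 1875 genes) to -0.53 in the longest (4557 to 19821 nt, 1873 genes), or from 0.32 to -0.27 with TMM scaling. Median transcript length was 817 nt in the ribosomal protein list, 504 nt in the histone list and 4805 nt in the chromatin list.

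**Figure D4:**
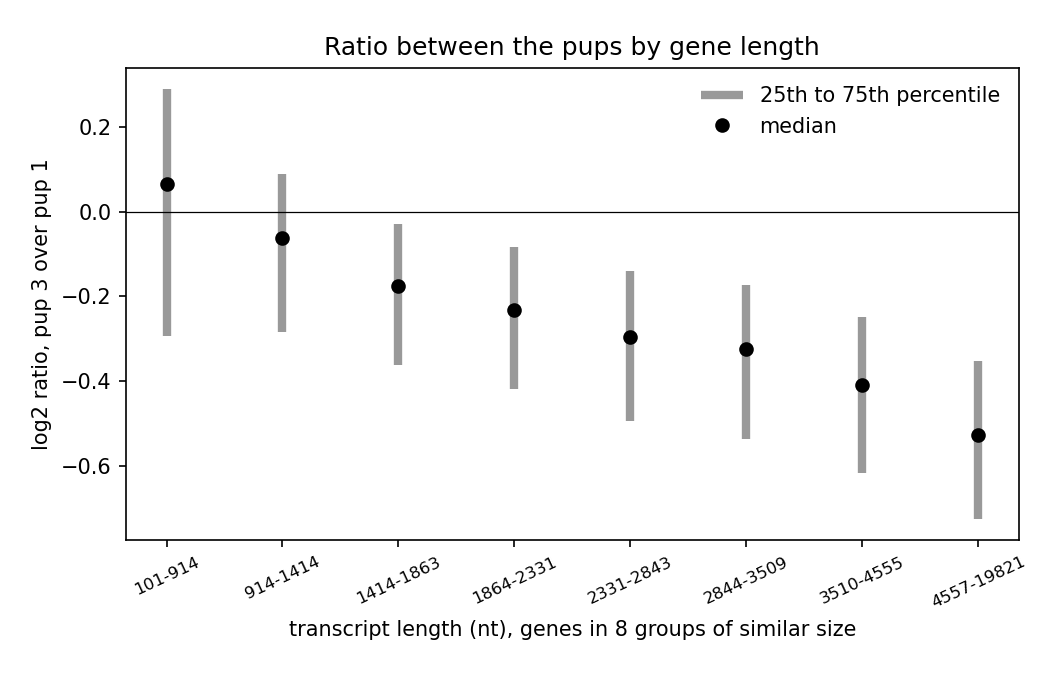
Log2 ratio of pup 3 over pup 1 in 8 groups of genes by transcript length in nt, with the median as a point and the 25th to 75th percentile as a bar. The median falls from 0.064 in the shortest group to -0.53 in the longest, and with TMM scaling from 0.32 to -0.27.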

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

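None of the tests in this part were chosen after the result was seen. The entries with numeric identifiers and tRNA-like lengths, which no comparison used, held 4.63 expected counts in pup 1, above the 3 counts that a count of 0 allows, and 2.27 in pup 3, over 26248 entries. No biological explanation was tested.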

How the results depend on the processing

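Corrections for and matching on gene length were chosen after the result was seen. No paired analysis was possible because the samples form 1 group. The count of detected genes stayed within 1.5 times 14389 under every setting run, between 14595 and 15309 with 1 pup alone. The number of lists above the median detected gene was 18 and 17 with 1 pup alone, and the nuclear protein-coding share 81.5% and 85%, against 93.3% by expected counts, where division by length is not applied. Of 44 list levels, 12 moved by more than 1 SD with members of 1 TPM or more only, 9 with rescaled TPM, 5 with posterior means and 3 and 6 with 1 pup alone. With 1 pup the count of pairs past 3 SD has no value; it was 20 or 21 under the settings run, and 22 isoform genes kept 1 leading transcript in both pups with posterior means. Of 24 pair ratios, 9 moved by more than 1 SD with a pseudocount of 1 and 16 with library-scaled counts. Of the pairs within 3 SD, Slc17a6 over Slc17a7 changed sign with library-scaled counts (log2 0.11, against -0.46) and, like Drd1 over Drd2, with pup 1 alone. Pearson's r was 0.972 with a pseudocount of 0.1, 0.993 with no filter and 0.982 at a mean TPM of 10 or more, and the spike-in r was 0.996 with 10 or more counts in both pups (5 spike-ins). The coefficient of variation was 0.186 with no filter, 0.162 with a minimum count of 50 and 0.161 for protein-coding genes. Against 596 differing genes there were 252 with TMM and 222 with ERCC scaling, 501 with posterior mean TPM, 2538 at 1.5-fold, 28 at 4-fold, 997 with no TPM filter, 161 at a mean TPM of 10 or more and 178 after correction for length, level and GC. The counts of lists outside, 19 to 23, cannot change under TMM or ERCC scaling, which move every gene alike. Among the 22 lists outside the central 95%, medians did change sign: TMM, ERCC and corrected values were 0.21, 0.39 and 0.20 for intermediate progenitors, 0.25, 0.44 and 0.33 for cell division, 0.19, 0.37 and 0.13 for microglia, 0.20, 0.38 and 0.25 for endothelial and 0.23, 0.42 and 0.40 for pericyte genes. Immature neurons were at 0.061 and 0.24 with TMM and ERCC scaling, imprinted genes at 0.061 with ERCC scaling, and immediate early genes at -0.0053 with members of 1 TPM or more only. Among the 22 lists inside, 10 medians changed sign with TMM scaling, 18 with ERCC scaling and 10 after correction. TMM and ERCC scaling add 1 shift to every gene, and for the other settings the cause was not tested. The spike-in shift rests on 334 and 278 counts (SE 0.117).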

Other observations

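The tests of the slope among non-neural genes, of the corrected diencephalic list and of Y-linked counts in pup 3 were chosen after the result was seen, as were the neutrophil lists, the look at fixed lists for cortical tissue and the correction for length, level and GC. Neutrophil genes, written as a list of 9 after the values of S100a8 and S100a9 had been seen, were all higher in pup 3, with a median log2 ratio of 0.97. TMM and ERCC scaling raise pup 3 and could not change that direction. Without S100a8 and S100a9, which prompted the list, the median of the other 7 was 0.60 (percentile 99.8 of lists matched on mean TPM), or 0.26 with a pseudocount of 1. Of the 7, 1 had a mean TPM of 1 or more, so the median rests on few counts. Erythroid genes, of another blood lineage, were higher too (0.43, percentile 99.97). Levels of the neutrophil genes were low: S100a8 had 4.94 and 15 TPM in pups 1 and 3, Ngp 1.25 and 2.55 and Camp 0.4 and 1.49.

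The tables argue against the trend with gene length, level and GC content as the whole cause of the lower diencephalic values in pup 3, since the median of the fixed list after correction for it, -1.18, stayed at percentile 0 of matched lists. A different share of diencephalic tissue in the 2 samples may contribute: 22 further marker genes, not all exclusive to that region and 13 of them at a mean TPM of 1 or more, had a corrected median of -0.71 (percentile 0; -1.06 as deposited), with Ntng1 at 27.8 and 9.54 and Zic4 at 41.5 and 20.4 TPM in pups 1 and 3. A different share of cortical tissue stays open: 10 further cortical genes had a corrected median of 0.59 (percentile 100; 0.23 as deposited), with Mef2c at 150.3 and 186, Rprm at 179 and 204 and Hs3st4 at 15 and 8.06 TPM. Of the fixed lists, upper-layer genes lay above matched lists once corrected (0.23, 99.1) but inside as deposited (-0.14, 89.2, against a median of -0.28), and corrected values of deep-layer (-0.02, 32) and forebrain identity genes (0.059, 65.4) lay inside and glutamatergic genes, not all cortical, below (-0.29, 0.06). Dissection and differences between the animals were not told apart by any test, and the design names no biological contrast.

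Longer genes were lower in pup 3, with a slope of -0.127 log2 units per doubling of length (bootstrap interval -0.15 to -0.104). The slope among 40 non-neural marker genes, -0.232 (-0.295 to -0.165), argues against fewer neurons in pup 3 as the whole cause. It cannot tell whether fewer neurons add to the trend across all genes. A difference between the libraries in transcript coverage or RNA integrity may contribute, as the slope between transcripts of the same gene was -0.0243 (-0.0311 to -0.0167, 5980 genes). That slope is much smaller than the one across genes, so most of the trend is left open, as is another makeup of the non-neural cells, and the design names no biological contrast.

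Y-linked genes and Xist were measured in different pups. The tables argue against reads of X-linked homologues assigned to Y-linked genes, with 1 count over the 4 Y-linked genes in pup 3 and 6965 in pup 1. Pups of different sex is a candidate explanation: 4 X-linked genes that escape inactivation had a corrected median at percentile 99.99 of matched lists, and 3 of the 4 were higher in pup 3 before correction, with Eif2s3x at 59.1 and 78.8 TPM and Kdm6a, the exception, at 6.17 and 5.99 in pups 1 and 3. Sex was not recorded, so this stays a hypothesis. With 1 library per pup, a difference in sex could not be told apart from any other difference between the pups.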
